A study of Caenorhabditis elegans with 2 samples.

How the data were processed

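The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists from whole Caenorhabditis elegans young adults. Per the labels, the worms were young adults of 67 hours that had been synchronised as L1 larvae starved after bleaching. They carried a transgene with C06A6.2 tagged by TY1, EGFP and 3xFLAG and with unc-119(+), in an unc-119 mutant strain, and the immunoprecipitation used an antibody to GFP. Chromatin was sheared by sonication, with a fragment size range of 200 to 800 given in the labels. There were 2 samples, which the labels number as biological replicates 1 and 2 of a single group. No second group, no untagged strain and no control library was analysed here, so every comparison is between the replicates, between peaks and positions in the genome, or between groups of genes.

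The files held 8 peak lists in ce11 coordinates, per the deposited text files that describe them. Each replicate had a ranked list and a list thresholded on the irreproducible discovery rate (IDR), a measure of how repeatable a peak's rank is. Both replicates together had 2 ranked lists and 2 thresholded lists, named conservative for the version labelled so and optimal here for the other. The replicates' own lists came from each replicate's filtered alignments, and the joint lists from both replicates' alignments. Each was derived with a further input shared by both replicates, whose role the description did not state; tracks of fold change over control, not used here, list the same input. The thresholded lists were derived from another input that the ranked lists did not use, and its role was not stated either. Which of the joint ranked lists came from the 2 replicates was tested on the files. In 1 of them, 67.7% and 65.8% of the member intervals were intervals of the ranked lists of replicates 1 and 2, against 5.63% and 0% in the other. The first is called here the ranked list of the 2 replicates and the second the ranked list of the pseudoreplicates. The aligner, the peak caller and their versions are not given in the sources used here.

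The authors' deposited signal is the peak caller's value per peak, higher where enrichment is stronger. Its scaling is not given in the sources used here. The deposited IDR score is a whole number of at most 1000 that falls as the IDR rises, and the deposited global IDR is a score on a −log10 scale. Both were used only to describe the threshold. Every peak of the 4 thresholded lists was also in the matching ranked list, with a score of at least 830, which was an IDR of at most 1.00%. Of the ranked peaks at or above that score, 31 were missing from the conservative list, 29 from the optimal list, 24 from that of replicate 1 and 17 from that of replicate 2. Signal was used to describe, rank or filter peaks within a list and, for peaks found in both replicates, to compare their order. The signal of a named peak in each replicate is that of the overlapping peak in the replicate's ranked list. The column of peak p-values held a single constant and was not used, nor were 4 columns of member signals in the joint ranked lists.

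The number of reads was not in the files used, so the depth of each library is unknown. Precision therefore comes from numbers of peaks and genes. Shares carry 95% Wilson intervals, which cover counting error only. Widths were largely fixed by the caller: 1129 of the 1346 conservative peaks were 320 bp wide, so positions were taken at the deposited summit.

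The conservative list was the main peak set. Annotation was Ensembl release 115 on WBcel235, the assembly that ce11 names, and no peak or gene ended beyond its chromosome. A promoter was the 500 bp on either side of any of 29304 transcription start sites (TSSs) of 19973 nuclear protein-coding genes. Summits were assigned in order to promoters, to the 500 bp around 5′ ends of non-coding RNA genes, to coding exons, UTRs, introns and intergenic sequence. Numbers per class were compared with 1000 random placements within each chromosome (permutation p, one-sided for the promoter share, two-sided with Benjamini-Hochberg adjustment over 6 classes and over 5 small RNA classes). The smallest p that 1000 placements can give is 0.000999, or 0.001998 two-sided. Chromosomes were compared with their share of protein-coding genes by a two-sided exact binomial test adjusted over 6 chromosomes.

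Overlap between replicates was counted at 1 bp or more and compared with 1000 random placements of the other list. Signal was correlated across overlapping peaks, with 1000 bootstrap draws for the interval. A gene was counted as having a peak when a conservative summit lay within 500 bp of any of its TSSs. In each of 21 gene lists, the genes with a peak were compared with all other protein-coding genes by a two-sided Fisher's exact test, adjusted over the 21 lists. The lists were ribosomal proteins, histones, translation factors, proteasome, mitochondrial respiratory chain, mitochondrial ribosome, V-ATPase, splicing, heat shock and chaperones, detoxification, cuticle collagens, major sperm proteins, vitellogenins, cell cycle and DNA replication, transcription factors, nuclear receptors, and markers of germline, intestine, muscle, neurons and epidermis. Each of 2080 6-mers, counted with its reverse complement, was compared between the 50 bp on either side of the summit and a window of that width centred 300 bp away (McNemar's exact test, adjusted over all 6-mers).

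The gene lists, the tests and the rule for named items were fixed before the data were examined. Named are the 20 conservative peaks of highest signal with their genes, C06A6.2 and unc-119, the 4 members of highest signal in each gene list past an adjusted p of 0.05, the 6 transcription factors of highest signal, and the 5 6-mers of smallest p and the depleted 6-mer of smallest p, which was among them. Others are named as examples chosen after their values were seen. Alternatives fixed at the same time were the optimal list, each replicate's own thresholded list (leaving out the other replicate), the conservative peaks of higher signal, windows of 250 and 1000 bp, other overlap rules, ranked summits or genes with a ranked summit as background, neighbouring genes counted once, shares of bases, wider 6-mer windows, matched 6-mer backgrounds and smaller rank bins. Leaving out a replicate meant using the other's own list, since peaks could not be called again. Alternatives added after the data were seen were GC strata for the gene lists, 8-mers, X and autosomes apart, piRNA genes left out, peaks near tRNA genes left out, and the other ranked lists at the transgene loci. The tests of miRNA and piRNA genes, of the side of the TSS and of the promoter share on X were also added then. A first look at the 6-mers and 8-mers had used another random choice of flank sides; values are from the seeded choice alone.

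The procedures were tested on simulated data of the same size. With 40% of summits planted near TSSs, the promoter share came out at 53.2% against 22.8% for random placements. In 10 runs over 19973 genes a planted gene list was called 10 times, with 1 call among 210 tests of lists with nothing planted. A planted 6-mer ranked first, 0 of 2080 6-mers were called with nothing planted, and 813 shared peaks were found where 807 had been planted. The planted gene list was that of the proteasome, with summits placed near its TSSs, and planted shared peaks were exact copies. The 6-mer simulation compared flank windows with flank windows, so it held no GC gap like that between summits and flanks. These simulations show that planted patterns are recovered, not the error rate or power in data like these. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.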

Results

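Binding of a tagged C06A6.2 protein was profiled by ChIP-seq in whole young adult worms of strain OP810, as 2 biological replicates of a single group. C06A6.2 (WBGene00015507, chromosome IV, 7846622 to 7854409, plus strand) is the gene whose product carried the EGFP tag. The assay is labelled as transcription factor ChIP-seq and asks where in the genome the tagged protein is found. The conservative list held 1346 peaks on the 6 nuclear chromosomes, with a median signal of 87.4. The replicates' own thresholded lists held 748 and 790 peaks, and their ranked lists 31655 and 28508. Depth is unknown.

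The peaks of highest signal were found in both replicates. The peak of highest signal in the conservative list (1433) lay on chromosome II at 10033557 to 10033856, 468 bp from the TSS of mtcu-2. It had a signal of 657 in replicate 1 and 780 in replicate 2. The next peaks were on chromosome III, 195 bp from the TSS of Y22D7AL.10 (1618967 to 1619273, signal 1146) and 62 bp from that of tasp-1 (10759094 to 10759412, signal 1135). Each of the 20 conservative peaks of highest signal was in both replicates' own thresholded lists. This would follow largely from the thresholding, which favours peaks of high rank. Of the 748 peaks of replicate 1, 504 overlapped a peak of replicate 2, which was 67.4% (95% Wilson interval 63.9 to 70.6) against 0.433% for random placements (one-sided permutation p = 0.000999, the smallest that 1000 placements can give). In the other direction the share was 502 of 790, or 63.5% (60.1 to 66.8), against 0.414% (permutation p = 0.000999, again the smallest possible).

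Sites that were missing from a replicate's own list had lower signals. Since these lists were thresholded on the repeatability of peak ranks, a difference of this kind would follow from the thresholding alone. Among conservative peaks, the 519 that overlapped both replicates' own lists had a median signal of 140, while the 437 that overlapped neither had 69.2. A further 196 overlapped the list of replicate 1 alone (median signal 81.2) and 194 that of replicate 2 alone (88.7). Across the 504 overlapping pairs the signals of the replicates were correlated (Spearman's rho 0.790, bootstrap interval 0.740 to 0.836, Pearson's r of log2 signal 0.809). Each replicate 1 peak was paired with its strongest partner, and some replicate 2 peaks were used more than once. The bootstrap does not take this reuse into account. Pairing by summits within 100 bp gave 479 pairs, with a rho of 0.816 and an r of 0.884. Either correlation is across peaks, which are not independent replicates, and no correlation across samples can be had from 2 samples. Replicate 2 had the higher signal by a median factor of 1.17.

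**Figure D1:**
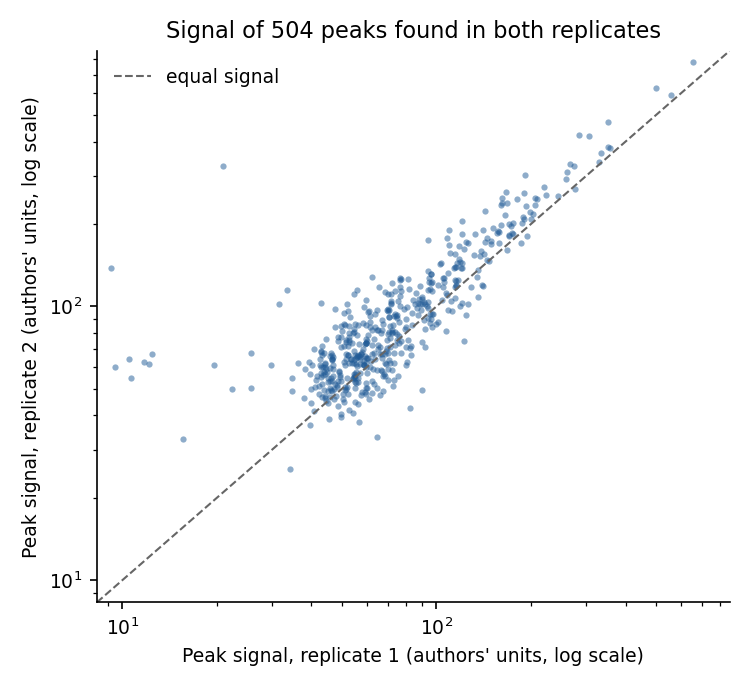
Authors' peak signal in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes. Each point is 1 of the 504 thresholded replicate 1 peaks that overlapped a thresholded replicate 2 peak, with its strongest partner there. The dashed line marks equal signal. Points follow the line, with rho 0.790 and a median ratio of replicate 2 to replicate 1 of 1.17.

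Promoters of protein-coding genes and the neighbourhoods of non-coding RNA genes held more of the summits than random placement gave, and coding exons and introns held fewer. Promoters took 577 of 1346 summits, 42.9% (40.3 to 45.5), against 22.7% for random placements (permutation p = 0.000999, the smallest possible). Within promoters, 473 of 577 summits (81.98%, 78.6 to 84.9) lay upstream of the nearest annotated TSS (exact binomial p = 3.69e-57). These TSSs are annotated transcript 5′ ends, and where transcription starts was not measured here. Among the peaks of highest signal, promoter summits included those at rpl-3 and rpl-35, which encode proteins of the large ribosomal subunit, npp-18, a nucleoporin gene, and unc-85, a histone chaperone gene. Non-coding RNA genes took 20.4% of summits against 8.52%, coding exons 3.20% against 17.01%, introns 10.2% against 24.3%, UTRs 1.56% against 2.69% and intergenic sequence 21.8% against 24.8%. All 6 classes were past an adjusted p of 0.05, the highest being 0.00999.

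The share of coding exons was 1.65% without replicate 1, 2.81% without replicate 2 and 1.63% among the peaks of higher signal, and the promoter share with a window of 250 bp was 28.3% against 12.1% at random. In the replicates' own, shorter lists the calls for UTRs and intergenic sequence were lost (adjusted p values of 0.0695 to 0.116) while the ratios to random stayed close, at 0.610 and 0.591 against 0.581 for UTRs and 0.881 and 0.898 against 0.879 for intergenic sequence. The call for intergenic sequence was also lost among the 673 peaks of higher signal (0.170). Ranked summits outside the thresholded peaks were in promoters in 25.6% of 34466 cases, below the conservative share (odds ratio 2.18, Fisher's exact p = 4.21e-41).

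**Figure D2:**
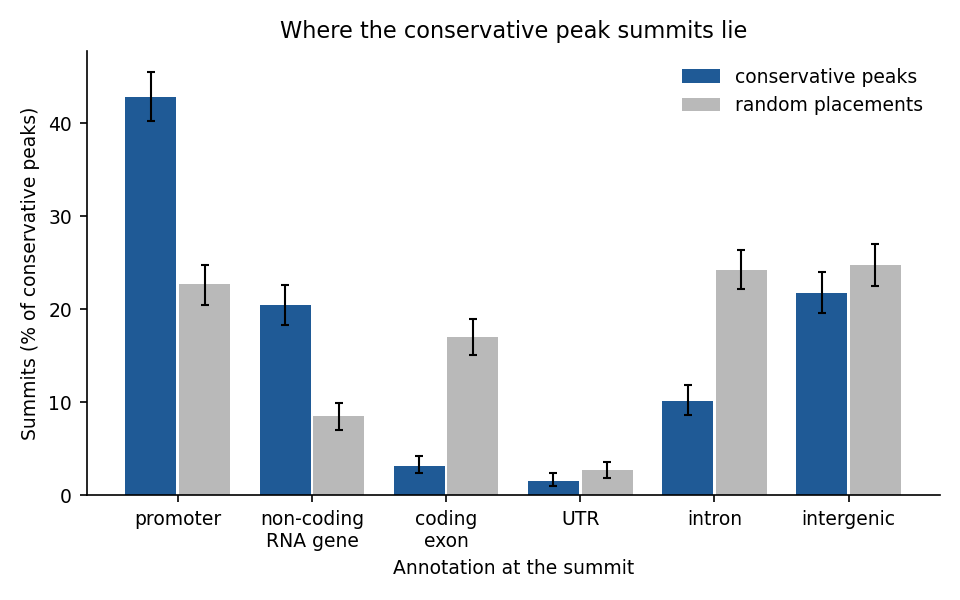
Share of the 1346 conservative summits in each annotation class (blue, with 95% Wilson intervals) beside the mean of 1000 random placements (grey, with the central 95% of placements). Promoters stand at 42.9% against 22.7% and coding exons at 3.20% against 17.01%.

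Of the remaining peaks among the 20 of highest signal, those in promoters were near F44E7.4 (chromosome V, 5777040 to 5777303, signal 672), rpl-20 and Y17G9B.5 (chromosome IV, 4749963 to 4750194, signal 568), set-16 and drr-2 (chromosome III, 13643600 to 13643862, signal 549) and K08F11.1 (chromosome IV, 4725506 to 4725733, signal 533). A peak with signal 499 lay in an intron of let-268 (chromosome II, 10034856 to 10035070). Another, with signal 493, lay 23 bp from sls-2.1, a spliced leader RNA gene (chromosome II, 5844672 to 5845024). A further peak, with signal 730, lay within the non-coding RNA gene F26F4.14 (chromosome III, 4899720 to 4900084). In intergenic sequence, 3 of the peaks had a pseudogene as the nearest gene, with signals of 822 (chromosome II, 5346448 to 5346707), 725 (chromosome V, 14038716 to 14038981) and 493 (chromosome IV, 4727928 to 4728154). The other intergenic peaks had as nearest genes the lincRNA gene M04F3.7 (chromosome I, 4769485 to 4769774, signal 700), the piRNA gene 21ur-13313 (chromosome III, 4281959 to 4282438, signal 620) and the tRNA gene WBGene00014538 (chromosome X, 11093973 to 11094349, signal 470).

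Genes for tRNAs, snRNAs and snoRNAs stood out among the non-coding genes. Summits near each kind of gene were counted whatever their class, so summits assigned to promoters are included. The counts are therefore not parts of the non-coding RNA class above. Within 500 bp of a tRNA gene lay 101 summits, 7.50% against 0.557% at random, and 16.99% of the 612 tRNA genes had a summit in reach (9.97% without replicate 1 and 7.52% without replicate 2). The snRNA genes, whose products act in splicing, had 23 summits (1.71% against 0.111%), and the snoRNA genes, whose products guide modification of other RNAs, had 66 (4.90% against 0.334%). Near miRNA genes the share was 1.04% against 0.242%, and near piRNA genes it was lower than at random, 1.78% against 3.91%. The adjusted p was 0.001998 for each of the 5 classes, the smallest that the placements can give.

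Along the ranked list of the 2 replicates, the promoter share fell from 44.5% (41.5 to 47.6) among the first 1000 peaks to 36.9% (33.96 to 39.9) for ranks 1001 to 2000 and 32.2% (29.4 to 35.2) for ranks 2001 to 3000. From ranks 7001 to 8000 (23.4%) onward the bins of 1000 peaks went up and down between 22.8% and 27.1%, and the last 238 peaks stood at 21.01%. In bins of 500 peaks the first bin stood at 48.4%.

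Chromosomes X and III held more peaks than their share of protein-coding genes, and chromosome V held fewer. X had 267 peaks, 19.8% (17.8 to 22.1) against 13.7% of the genes (exact binomial test, adjusted p = 1.22e-09). By the same exact test chromosome III had 229 peaks, 17.01% against 13.2% (adjusted p = 0.000156), and V had 220, 16.3% against 25% (adjusted p = 1.21e-13). Chromosome I was above its share (16.7% against 14.4%, exact binomial test, adjusted p = 0.0214), IV below it (13.7% against 16.4%, adjusted p = 0.00867), and II did not differ past the threshold (16.4% against 17.3%, adjusted p = 0.428). X also holds 276 of the 612 tRNA genes, and 50 of its peaks lay near them. With peaks near tRNA genes left out, X stood at 17.4% (exact binomial test, adjusted p = 0.000400). Against shares of bases, X and I were no longer past the threshold of the exact test (adjusted p = 0.0574 and 0.103), and the calls for I and IV were lost without replicate 2 (0.310 and 0.102) and among the peaks of higher signal (0.0631 and 0.0824). The ratios of I and IV to their gene shares were 1.16 and 0.832 in the main list. They were 1.095 and 0.846 without replicate 2, and 1.196 and 0.841 among the fewer peaks of higher signal.

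At the level of genes, 3.27% of 19973 had a conservative peak at a promoter. Of the 21 gene lists, 7 had a larger share than all other genes, and none had a smaller share past an adjusted p of 0.05. The first were heat shock and chaperone genes, with 21 of 74 (28.4%, 19.4 to 39.5; odds ratio 12.1, Fisher's exact test, adjusted p = 2.91e-13), and genes for cytosolic ribosomal proteins, with 21 of 81 (25.9%, 17.6 to 36.4; odds ratio 10.7, adjusted p = 1.06e-12). Both lists also passed in each replicate's own thresholded list, with odds ratios of 15.13 without replicate 1 and 15.07 without replicate 2 for chaperones, and of 13.42 and 17.86 for ribosomal proteins. Among genes with a ranked summit the odds ratios were lower, 6.45 for chaperones and 4.99 for ribosomal proteins.

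Among chaperone genes, the peaks of highest signal were at F44E5.4 and F44E5.5 (424), cct-8 (360) and hsp-90 (287). F44E5.4 and F44E5.5 are near-identical Hsp70 genes that share a single peak between them, so they are uncertain as separate genes. The cytosolic Hsp70 gene hsp-1 (221), hsp-110 (157), the endoplasmic reticulum chaperone genes hsp-3 (185), enpl-1 (139) and crt-1 (117), the mitochondrial Hsp70 gene hsp-6 (109) and 7 DnaJ-type co-chaperone genes were on the list as well, as examples chosen after their values were seen. For 16 of the 21 the peak was in both replicates' own lists. Among ribosomal protein genes, rpl-3 (726), rpl-35 (711), rpl-20 (568) and rpl-15 (418) led, and 17 of the 21 had their peak in both replicates' lists. The median signal at these peaks was 166 for chaperones and 200 for ribosomal proteins, above the 87.4 of the whole list. With a window of 250 bp the ribosomal protein call was lost (odds ratio 2.46, Fisher's exact test, adjusted p = 0.224), while in the other alternatives the adjusted p was at most 1.26e-06.

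Mitochondrial respiratory chain genes had a peak in 11 of 72 cases (15.3%; odds ratio 5.41, Fisher's exact test, adjusted p = 0.000145). They were led by cox-5A (362) and cox-5B (147), of complex IV, atp-1 (281), of the ATP synthase, and ndua-2 (215), of complex I. The translation factor list had 11 of 75 (14.7%, odds ratio 5.15, Fisher's exact test, adjusted p = 0.000161). It was led by ears-2 (407), iff-2 (320), the elongation factor gene eef-2 (241) and eef-1G (171). This list also takes in tRNA synthetase genes, ears-2 and tars-1 among them. Both lists also passed in each replicate's own list, but without replicate 1 the respiratory chain count fell to 6 of 72 (8.33%; odds ratio 3.87, Fisher's exact test, adjusted p = 0.0339). Among genes with a ranked summit the odds ratios were 3.12 for the respiratory chain and 2.94 for translation factors.

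Calls for 3 other lists were less firm. Cell cycle and DNA replication genes had 9 of 85 (10.6%; odds ratio 3.54, Fisher's exact test, adjusted p = 0.00764), led by cdc-48.1 (456), the centrosome gene spd-5 (272), pcn-1, which encodes PCNA (156), and the topoisomerase gene top-2 (113). Splicing genes had 7 of 68 (10.3%; odds ratio 3.42, Fisher's exact test, adjusted p = 0.0200), led by mog-4 (432), snr-4 (188), prp-40 (90.7) and rsp-2 (82.5). Histone genes had 8 of 81 (9.88%; odds ratio 3.27, Fisher's exact test, adjusted p = 0.0173), led by his-37 (345), the H2A.Z gene htz-1 (162) and the divergent pair his-5 and his-6 (94.9), but the 8 genes shared 5 distinct peaks. With neighbouring genes counted once, the histone list had 5 of 50, and its call was lost (odds ratio 3.595, Fisher's exact test, adjusted p = 0.0511). Many histone genes are near-identical copies, so those calls are uncertain. Without replicate 2 the histone count fell to 2 of 81 and the odds ratio to 1.23 (adjusted p 0.834), and the splicing odds ratio to 2.25 (0.369), while for cell cycle genes the call was lost with an odds ratio of 3.06 (0.101). Without replicate 1 the splicing call was lost too (odds ratio 2.65, 0.153). Over all alternatives the adjusted p ranged from 0.00419 to 0.101 for cell cycle genes, from 0.00346 to 0.369 for splicing genes and from 0.00785 to 0.834 for histones.

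The other 14 lists did not pass. Transcription factor genes had 15 of 337 (4.45%; odds ratio 1.39, 0.763 to 2.34; Fisher's exact test, adjusted p = 0.410). Those of highest signal were lin-54 (264), ztf-7 (254), dmd-7 (138), ceh-38 (129), zip-4 (123.7) and zip-2 (114). The stress-response regulators xbp-1 (100), atf-6 (94.2) and atf-4 (72.5), chosen after their values were seen, were among the 15. The peak of xbp-1 was in both replicates' own thresholded lists, those of atf-6 and atf-4 in that of replicate 2 alone. The signal of atf-4 was below the median of the whole conservative list. Nuclear receptors had 6 of 274. For the tissues that whole worms contain, the counts were 3 of 102 germline markers, 3 of 94 intestine markers, 2 of 66 muscle markers, 7 of 338 neuron markers and 3 of 219 epidermis markers. With a replicate left out these counts were 0 to 5, among them 0 of 66 muscle markers without replicate 1 and 1 of 219 epidermis markers without replicate 2. Detoxification genes had 2 of 218 (odds ratio 0.272, Fisher's exact test, adjusted p = 0.137; past the threshold at 1000 bp, 0.0214) and cuticle collagens 3 of 176, against 0 and 1 without replicate 2. Major sperm proteins had 0 of 63 and vitellogenins 0 of 6, counts that allow shares of up to 5.75% and 39.03% (upper Wilson bounds). The proteasome had 2 of 33, the V-ATPase 2 of 21 (past the threshold without replicate 1, with 3 of 21, Fisher's exact test, adjusted p = 0.0422) and the mitochondrial ribosome 1 of 71.

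Some peaks reach more than 1 gene, and the lists do not say which gene a peak belongs to. This was so for 131 of the conservative peaks, among them the peak counted for both lin-54 and rpl-12 (346 and 47 bp from the summit) and the peak counted for both hsp-110 and the proteasome gene rpn-3. Some single peaks count for more than 1 of the lists that passed, so those lists are not independent. Examples are the peak of ndua-2 (respiratory chain) and dnj-29 (chaperones) and that of prp-40 (splicing) and clu-1 (translation factors).

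**Figure D3:**
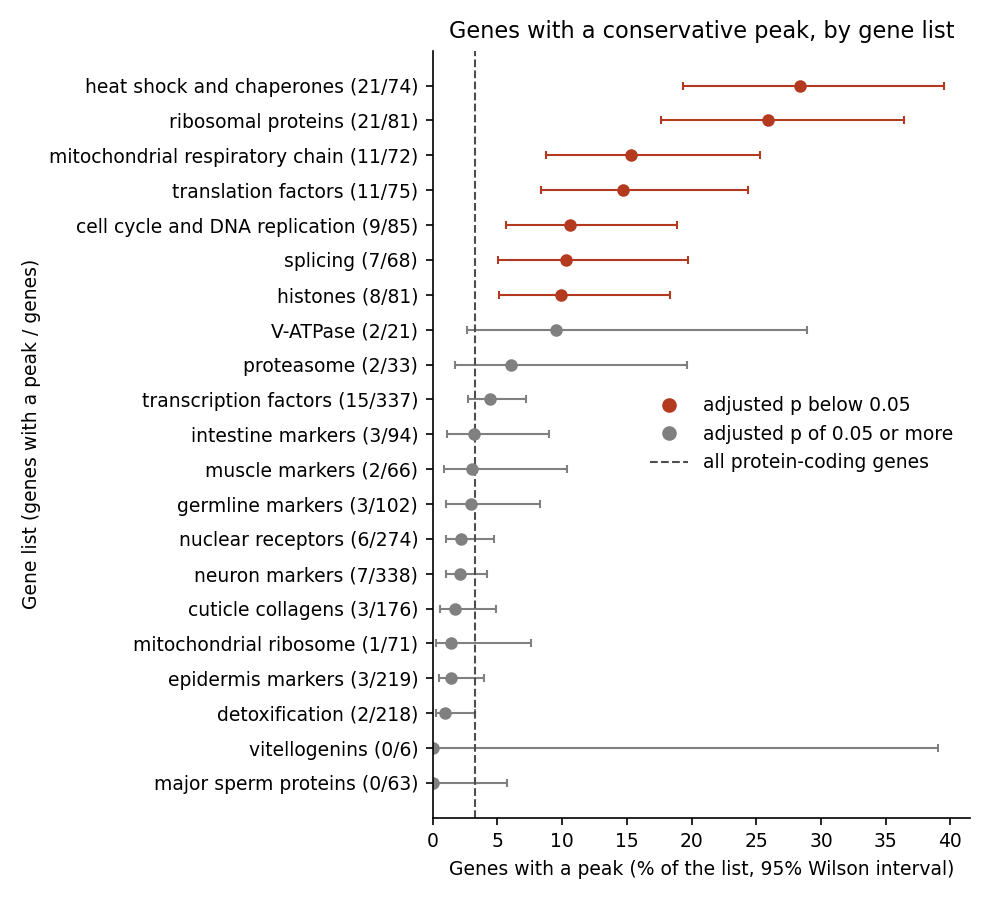
Share of each gene list with a conservative summit within 500 bp of a TSS, with 95% Wilson intervals; red points mark adjusted p below 0.05 and the dashed line marks all protein-coding genes (3.27%). Chaperones (28.4%) and ribosomal proteins (25.9%) lie farthest to the right.

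AT-rich words were rarer at summits than beside them, and GA-repeat and ACGCAG-type words were more common. AAAAAT was found at 20.7% of summits and 48.4% of flanks (McNemar's exact test, adjusted p = 1.34e-47), AAAATT at 15.9% and 40.9%, TAAAAA at 11.6% and 33.1%, and TTAAAA at 9.21% and 27.9%. GAGAGA was found at 24.4% of summits and 6.98% of flanks (McNemar's exact test, adjusted p = 8.20e-34). GACGCA (14.7% against 2.01%) and ACGCAG (15.5% against 2.82%), named after their values were seen, had adjusted p values of 2.36e-32 and 7.25e-29. In all, 582 of 2080 6-mers were more common at summits and 365 less common. Mean GC content was 47.6% at summits, 35.4% in flanks and 40.4% at ranked summits outside the thresholded peaks.

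Against ranked summits matched on GC content and promoter position (1344 pairs), the AT-rich words no longer differed past the threshold, AAAAAT standing at 20.7% against 19.9% (Fisher's exact test, adjusted p = 0.880). GAGAGA stood at 24.4% against 10.2% (Fisher's exact test, adjusted p = 1.09e-19), GACGCA at 14.7% against 4.54% (6.64e-17) and ACGCAG at 15.5% against 3.87% (2.31e-22).

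**Figure D4:**
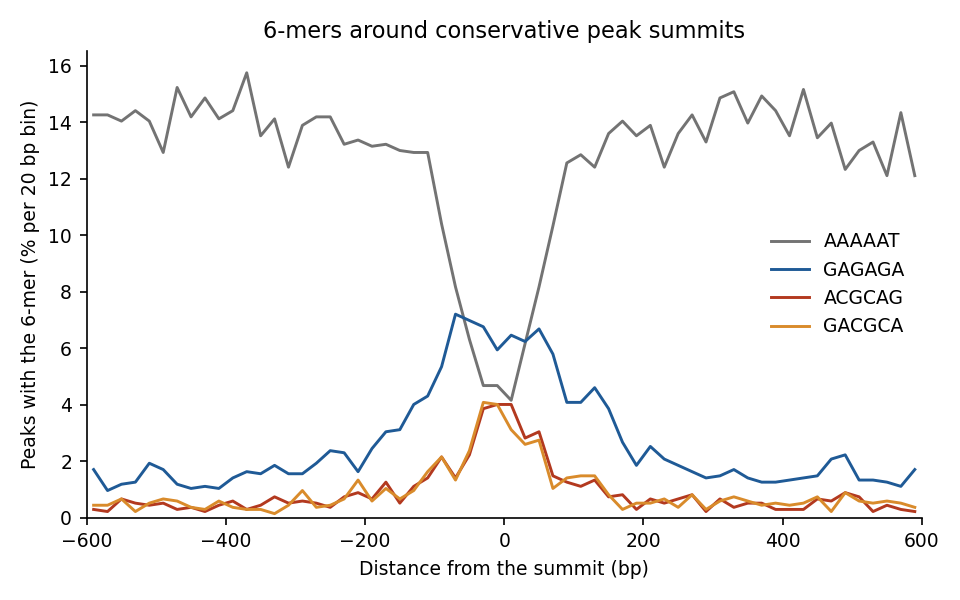
Share of conservative peaks with each 6-mer (either strand) in 20 bp bins, by distance in bp from the summit. AAAAAT dips to 4.16% in the bin just right of the summit, while GAGAGA, ACGCAG and GACGCA peak within about 100 bp of it.

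The transgene carries C06A6.2 and unc-119(+), so both loci were looked up in every list. Whether it adds copies of either native sequence was not measured. No peak of any of the 8 lists overlapped C06A6.2 or the 5 kb on either side, where the mean density of the ranked list of the 2 replicates would give 6.43 peaks. The stretch without a ranked summit was 63.5 kb long in replicate 1 and 74.7 kb in replicate 2, against median distances between neighbouring summits of 1.76 and 1.94 kb. The part without a summit in all 4 ranked lists ran from 7822945 to 7882465 on chromosome IV and held 9 protein-coding genes, among them flp-10 and kin-26. At unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935) the ranked list of the 2 replicates had 6 peaks where its mean density would give 5.89, and none was in a thresholded list.

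**Figure D5:**
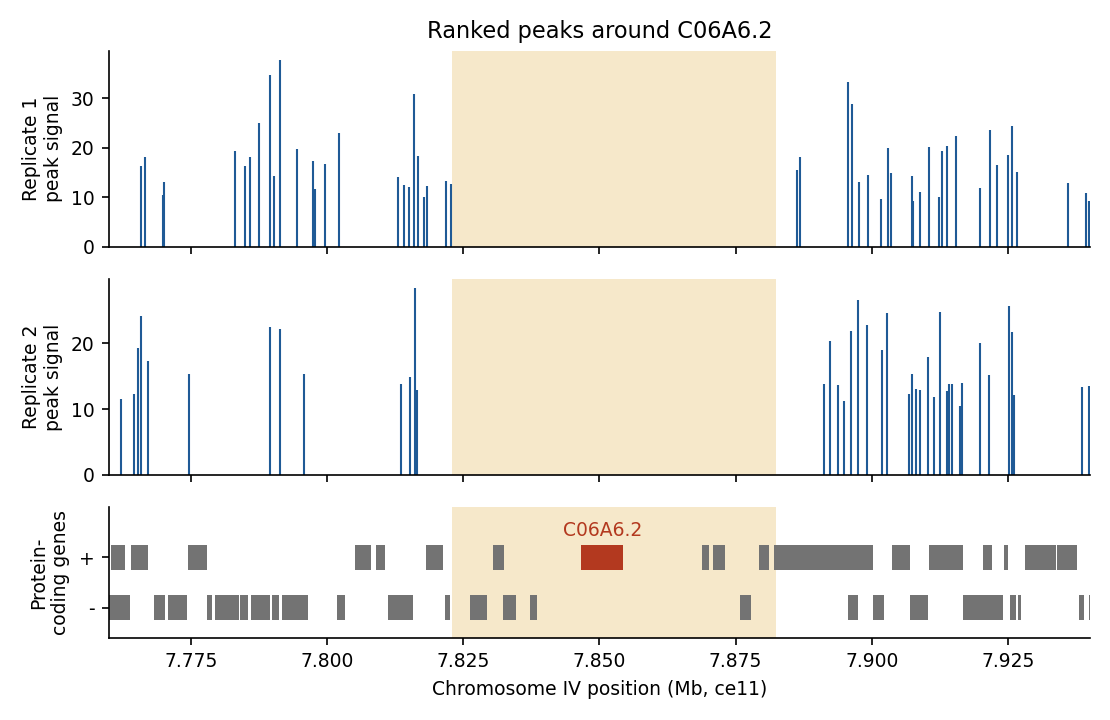
Ranked peaks around C06A6.2 on chromosome IV (position in Mb, ce11): the upper panels give the authors' peak signal at each summit in replicates 1 and 2, and the lower panel the protein-coding genes on each strand, with C06A6.2 in red. The shaded 59.5 kb holds no ranked summit in any of the 4 ranked lists.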

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

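The peaks described here were singled out after the result was seen; the measure of repeated sequence was chosen before its values were seen. What drew attention was signal in peaks that the thresholded lists leave out. The peak of highest signal in the ranked list of the 2 replicates, 1568, lay on chromosome X at 15811009 to 15811183, in intergenic sequence, and was in no thresholded list. It was among 31 peaks that passed the IDR score of the conservative list but were missing from it. Of the 50-mers in that peak, 0% occur once in the genome. Over the 31 peaks the median was 29.9%, with 24 below 50%, against a median of 100% over the conservative peaks, of which 43 were below 50%. Others among the 31 were a peak at 293338 to 293502 on chromosome X (signal 623) and a peak 108 bp from the ribosomal RNA gene rrn-4.2 on chromosome V (signal 72.0).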

How the results depend on the processing

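Tests with GC strata, 8-mers, X and autosomes apart, piRNA genes left out, peaks near tRNA genes left out and the other ranked lists at the transgene loci were chosen after the results were seen. No paired analysis was possible because the study has 1 group. Of 57 alternative values of the main results, 49 kept their direction and side of the threshold, or stayed within 1.5 times a count. The other 8 were as follows, and the cause was not tested. The promoter share of the first bin was 48.4% with bins of 500 peaks. Of the 6 chromosomes, 5 passed the test, 3 to 5 with a replicate left out, 3 with the 673 conservative peaks of highest signal and 3 by share of bases. The number of gene lists past the threshold ranged from 4 to 7 with a replicate left out, against 7. With matched ranked summits as background, 164 6-mers were more common and 192 less common at summits; with flanks as background these were 582 and 365. With 8-mers 317 of 31780 were more common.

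Of 569 alternative values of single lists, classes, words and genes, 505 kept their call, 48 lost it, 2 gained one and 14 changed direction. None of the 14 was past the threshold, before or after, except 3 AT-rich words that had been past it. Odds ratios crossed 1 for nuclear receptors (0.621 to 1.09 with a replicate left out), germline markers (0.842 to 1.48, 1.34 at 1000 bp and 1.11 among genes with a ranked summit), intestine markers (0.452 to 1.06, and 1.098 with neighbouring genes counted once), muscle markers (1.02 at 1000 bp and 1.00 with neighbouring genes counted once) and the mitochondrial ribosome (1.28 at 1000 bp). The V-ATPase odds ratio fell to 0 at 250 bp, and chromosome II at 16.4% was above its share of bases. Against matched ranked summits, AAAAAT (20.7%), TAAAAA (11.6%) and TTAAAA (9.23%) were slightly more common at summits. Of 44 named genes, 44 had a peak in the optimal list, 40 to 43 with a replicate left out, 43 among the peaks of higher signal, 27 at 250 bp and 44 at 1000 bp. Depth is unknown, so whether a gene without a peak lacks binding or lacks reads cannot be told from these lists.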

Other observations

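The tests of X against autosomes, of 8-base words, of vitellogenins, sperm and muscle genes pooled, of the chance length of the stretch at C06A6.2 and of the transgene copies were chosen only after the results were seen, as were the GC strata and the split of the gene lists into parts. Peaks on X were placed unlike those on the autosomes. Of the 267 X peaks 70 had a promoter summit (26.2%, 21.3 to 31.8), against 507 of 1079 on autosomes (46.99%, 44.03 to 49.97; Fisher's exact p = 5.79e-10). The corresponding shares of ranked summits outside the thresholded peaks were 21.5% and 26.7%. With conservative peaks near tRNA genes left out, the X share was 30.4%, against 39.9% (IV) to 54.9% (I) on single autosomes. Without replicate 1 the X share was 33.1%, against 47.5% (IV) to 54.8% (I). Without replicate 2 it was 27.9%, against 41.9% (III) to 53.4% (V). Among 8-mers, AGACGCAG was found at 8.84% of all conservative summits and 0.817% of flanks (McNemar's exact test, adjusted p = 4.62e-20), and AGAGAGAG at 5.28% and 0.446% (adjusted p = 8.62e-13).

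Some X peaks held the word GCGCAGGG within 100 bp of the summit. They numbered 15 of 267 on X (5.62%, 3.43 to 9.06) against 2 of 1079 on autosomes (0.185%, 0.0509 to 0.673; Fisher's exact p = 1.93e-09), with 1 of 267 and 0 of 1079 in windows 300 bp away, and 10 of the 15 were among the 20 X peaks of highest signal. The word was picked from 4 words tried, after their counts had been seen and partly for its likeness to known X recruitment elements, so neither this p nor the next, which rests on the same 17 peaks, is corrected for that choice. More copies of the word on X (4.57 per Mb against 2.82) would put 28.6% of such peaks there, against the 88.2% observed (exact binomial p = 5.14e-07), a gap that copy number alone would not give, though the choice of word may have widened it. A hypothesis that stays open is that these are sites of a factor that acts mainly on X, such as the dosage compensation complex. Under it, the tagged protein may be recovered with that factor. This cannot be told apart here from recovery by any antibody because no other factor and no untagged strain was analysed.

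The 7 gene lists with more peaks include those for protein synthesis and folding. Detectability of a promoter was measured only as having a ranked summit or not. In that form the tables argue against it as the whole cause for 6 of the 7. Their odds ratios kept a lower 95% bound above 1 among genes with a ranked summit (2.90 to 6.45). Over strata of promoter GC content, taken over 200 bp on either side of the TSS, 6 of 7 also kept such a bound (2.93 to 12.02). That argues against GC content this near the TSS as the whole cause for those 6. Many summits lay farther away: with a window of 250 bp, 4 of 81 ribosomal protein genes had a peak. GC content at the summit was not stratified, so its part stays open. Differences in degree of detectability stay open too. A ranked summit measures them poorly: outside the thresholded peaks, 25.6% of ranked summits were in promoters, against 22.7% for random placements of the conservative summits. Among genes with a ranked summit the odds ratios fell from 12.1 to 6.45 for chaperones and from 10.7 to 4.99 for ribosomal proteins. For the splicing list the first cannot be told apart, with the odds ratio going from 3.42 (1.32 to 7.52) to 2.72 (0.986 to 6.54), nor for histones the second, from 3.27 (1.36 to 6.83) to 1.93 (0.914 to 4.09), since both intervals also reach the original value. It stays open that highly transcribed genes may precipitate whatever protein is tagged: vitellogenins, sperm and muscle genes, taken as others with abundant transcripts, had an odds ratio of 0.443 with an interval of 0.0530 to 1.64 that decides nothing, and neither transcription nor an untagged strain was analysed. A biological explanation, binding of C06A6.2 at genes for protein synthesis and folding, was not tested, since the design has a single group.

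The stretch without ranked peaks over C06A6.2 is a further hypothesis. Chance is argued against, since at most 0.598% of the genome lay in stretches as long in either replicate's ranked list (0.954% in that of the 2 replicates and 1.36% in that of the pseudoreplicates), and so is sequence that short reads cannot place, since 98.6% of its 50-mers occur once in the genome. Extra transgene copies could raise a control there and so suppress peaks: the 59.5 kb shared by all 4 ranked lists would allow this, but it cannot be told apart from other causes because coverage of a control was not analysed here. No such stretch was seen at unc-119, the other gene that the transgene carries. There the ranked list of the 2 replicates had 6 peaks against 5.89 at its mean density. Whether the transgene's unc-119(+) matches the native sequence was not tested, so this does not decide. No biological explanation was tested.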
